A study of Mus musculus with 800 samples.

How the data were processed

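The series holds 800 single-cell libraries from mouse retina at embryonic day 15.5, labelled Tomato+ (400 cells) or Tomato- (400 cells). The deposited table gives counts per gene and cell, unnormalised whole numbers, with column headers ending in "umi". Whether these are unique molecules or reads is not stated in the sources used here: the median nonzero count was 16, and 34.4% of nonzero counts were below 5. The submitters' notes name Seurat 2.3, R 3.4.4 and the mm10 genome, while the aligner, the counting tool and the annotation are not given. The labels name SmartSeq2 for the libraries and the series title names C1. Of 801 columns, 1 matched no labelled cell and was not used. The table has 49585 gene rows and 49492 symbols, and 92.2% of its values are 0. The 93 repeated rows stayed in the totals and were never named. There were 0 identical cell columns and 0 spike-in rows.

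Cells with at least 1000 genes and at most 20% of counts in mitochondrially encoded genes were kept. This removed 73 Tomato+ and 38 Tomato- cells, all by the mitochondrial limit, and left 327 Tomato+ and 362 Tomato- cells. Sums over the kept cells were 86301166 counts in Tomato+ and 93484125 counts in Tomato- cells. Median mitochondrial shares were 5.69% and 6.16%, and median 18S rRNA shares 2.62% and 2.45%. Over all 40 cells of a title number before filtering, median totals ran from 127257 to 362038 in Tomato+ and from 185334 to 289217 in Tomato- cells. Title numbers 8 and 10 stood apart, with median totals of 148632 and 127257 and mitochondrial shares of 10.3% and 10.2%. The 4 genes with the largest shares of all counts were mt-Rnr2 (4.51%), Rn18s-rs5 (2.51%), Malat1 (1.61%) and mt-Rnr1 (1.40%).

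Classes came from both groups clustered together with scanpy 1.11.5 and anndata 0.12.19. Each cell was scaled to the median total and log-transformed, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 8 clusters. Mitochondrial, ribosomal protein, 18S and haemoglobin genes were left out of the variable genes, as were the lists for ipsilateral, contralateral, serotonin and positional identity. A cluster took the class with the largest share of its markers at least 2-fold above the lower quartile of the clusters and with at least 5 counts in at least 20% of the cluster's cells, given at least 3 such markers. A name was withdrawn where the cluster's leading genes belonged to another class. The reference level and the rule on leading genes were set after the clusters had been seen. Cluster 3, unnamed under them, held 20.7% of Tomato- and 2.14% of Tomato+ cells. Clusters 0, 1, 2 and 6 were RGC-like, clusters 4 and 7 progenitor-like and cluster 5 neurogenic precursor-like. The RGC-like class held 318 Tomato+ and 117 Tomato- cells, the progenitor-like class 2 and 115, and the neurogenic precursor-like class 0 and 55. Over the alternatives, the number of Tomato- RGC-like cells ran from 85 to 192. Leading genes, as definitions only, were Ubash3b and Car10 (cluster 0), Cntn2 and Ppp1r17 (1), Eomes and Pnoc (2), Fgf15 and Fosb (4), Neurog2 and Penk (5), Wbscr17 and Ephb1 (6) and Apoe and Mcm5 (7).

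For all kept cells and for the RGC-like class, counts were summed per group, divided by the group total and given as CPM. Log2 ratios are Tomato+ over Tomato- with a pseudocount of 10 CPM. Shares of cells with at least 1 and at least 5 counts are given, and shares after thinning each cell to 94783 counts, the 10th percentile of totals, which left out 33 Tomato+ and 36 Tomato- shallower cells. Each group is 1 pool with no animal per cell, so no p-value, standard error or count of changed genes was made from cells. For a count of 0, the share that 3 cells would give is stated as the upper limit. Gene lists are described by their median log2 ratio and its percentile among 10000 random lists of the same size matched on expression. TMM (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, both in R 4.3.3) differed between the groups by 0.12 and 0.14 on the log2 scale over all cells and by 0.043 and 0.044 in RGC-like cells. With the pseudocount, log2 ratios moved by less, that of Slc6a4 over all cells from 3.43 to 3.49 with TMM and 3.50 with median of ratios.

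Groups, comparisons, gene lists, the rule for naming genes and most alternatives were set before the data were examined. Named genes are Slc6a4, the members of the ipsilateral and contralateral lists, and the 10 highest and 10 lowest log2 ratios among genes detected in at least 10% of the cells of the higher group whose share differs by at least 10 percentage points in the same direction. Predicted genes, Xist and Y-linked genes were passed over. Of the other lists, members with the largest absolute ratios were to be named, but in some lists members with smaller ratios are named instead. The values of 1 gene of the progenitor list are not reported here. Of the 20 ranked genes, 13 over all cells and 7 in RGC-like cells were among the variable genes that shaped the clusters, and 8 and 7 lead a cluster. Gene positions are from GENCODE M21 on GRCm38, the assembly also called mm10, which holds 47240 of the symbols. Positions are 1-based.

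No cells were removed as doublets. Scrublet called 0 Tomato+ and 5 Tomato- cells, 2 of them RGC-like, and these were left out as an alternative. Other alternatives changed the cell filters, scaling, weighting of cells, pseudocount, detection limit, clustering and variable genes, or left out each title number in turn. Where title numbers were left out or the cell filters changed, the remaining cells were clustered and named again, so the RGC-like class could change. Titles also carry a row number from 1 to 40, and as an alternative chosen after the data were seen both groups were averaged over the rows that hold cells of both, with rows weighted equally. These were 40 rows over all cells and 38 rows in RGC-like cells. For the tests of technical explanations, 95% ranges over 10000 resamples of genes were used, and an explanation with such a range was set aside as the whole cause where the whole range lay outside what it required. Both rules were set after the first values had been seen. The range for low-level transfer crossed its mark of -5, chosen after its result was seen, and that for progenitor RNA in the hypoxia list crossed its mark of -0.4, set in advance. Held to these marks, both would have been left undecided. Both are left open. The test of low-level transfer assumed that passed counts stay below 5 in a cell, and that of progenitor RNA assumed 1 share for every gene. The steps were tested on simulated data with 200 changed genes among 49585. Log2 ratios lay within 0.25 of the truth for 98% of genes at folds of 0.25, 0.5 and 2 and for 100% at a fold of 4. All 20 ranked genes were simulated changes, and 100% of 240 simulated cells were given their class. For the ratios, cells of 1 type were simulated without added spread between title numbers, and the known shift in totals was corrected. Only well expressed genes were changed, and the simulated classes had markers set far apart. The simulation therefore does not show how title numbers or class borders affect the ratios and classes reported here. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.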

Results

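Single-cell RNA-seq libraries were made from retinas of Sert-Cre mice on the C57BL/6 background at stage E15.5. Sert-Cre expresses Cre recombinase under the control of Slc6a4, the gene of the serotonin transporter. In the developing mouse retina this transporter is known from retinal ganglion cells (RGCs) whose axons stay on the same side of the brain at the optic chiasm. The labels divide 800 cells into 400 Tomato+ and 400 Tomato- cells. Per the labels, retinas were dissociated with papain, strained and sorted by flow cytometry, and the sorting gate is not described. A filter on mitochondrial counts left out 73 Tomato+ and 38 Tomato- cells, and 689 cells were kept. Total counts per cell ran from 9653 to 644293 in Tomato+ cells, with a median of 271789. In Tomato- cells they ran from 16826 to 689788, with a median of 243410. The median number of genes detected was 4550 in Tomato+ and 3755.5 in Tomato- cells.

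No animal is named for any cell, so each group is 1 sample without replicates, and no test between the groups was made. Cell titles carry a number from 1 to 20, called the title number here, of which 1 to 10 are Tomato+ and 11 to 20 are Tomato-, with 40 cells each before filtering. The standard deviation (SD) of log2 CPM (counts scaled to the group's total) between title numbers, combined over both groups, is given as a measure of spread. It takes in technical differences and the sampling and mix of cells alike, since title numbers hold different cells. It cannot separate the label from differences between title numbers, since the title numbers do not overlap between the groups. Intervals are exact Poisson intervals for CPM and exact Clopper-Pearson intervals for shares of cells, both at 95%, and they cover counting error only. For a count of 0 cells, the share that 3 cells would make is given as the upper limit in place of the interval.

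Slc6a4, the gene whose driver gives the label, was compared first to ask whether the sorted cells carry its transcript. It was higher in Tomato+ cells, at 103.75 CPM (101.61 to 105.92) against 0.546 CPM (0.406 to 0.717) in Tomato- cells, a 190-fold difference in CPM. At least 1 count was found in 50.8% (45.2 to 56.3) of Tomato+ and 5.80% (3.63 to 8.73) of Tomato- cells. At least 5 counts were found in 36.7% (31.5 to 42.2) against 0.276% (0.007 to 1.53). The log2 ratio with a pseudocount of 10 CPM was 3.43, above the SD between title numbers of 0.37. Single title numbers lay between 53.3 and 154.3 CPM in Tomato+ and between 0 and 2.10 CPM in Tomato- cells, without overlap. With each cell thinned to 94783 counts, Slc6a4 was detected in 47.3% of Tomato+ and 1.84% of Tomato- cells. Progenitor-like Tomato- cells, which should lack the transporter, gave the background. Of these, 4.35% had at least 1 Slc6a4 count and 0 cells had at least 5, at a median total of 230343. Of the Tomato- RGC-like cells, 7.69% (3.58 to 14.1) had at least 1 count, at a higher median total of 332260, and 0.855% had at least 5. With cells thinned to 94783 counts, the share with at least 1 count was 1.89% (0.229 to 6.65), near that of all Tomato- cells. Before thinning, the cells with a count in cluster 1 were 5 of 35 Tomato- cells, or 14.3% (4.81 to 30.3). The gene lies on chromosome 11 from 76998603 to 77032340 (GRCm38, plus strand). The table holds 0 rows for a Cre or Tomato transcript, so neither could be measured.

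The classes of retinal cells were compared to ask which kinds of cell the label takes in. Of 689 kept cells, 435 were RGC-like. Of the Tomato+ cells, all but 9, or 97.2% (94.8 to 98.7), fell in clusters named RGC-like from a fixed list of markers that includes Pou4f2, Sncg and the neurofilament gene Nefm. Among Tomato- cells the RGC-like share was 32.3% (27.5 to 37.4). That share depended on the clustering and on leaving 1 cluster, described below, unnamed. It was 52.8% without title number 2, 53.4% without title number 14, 53.04% without title numbers 8 and 10 and 51.1% with 10 principal components. With RGC-like cells taken by at least 5 counts of RGC markers, without clustering, the shares were 64.8% of Tomato+ and 23.5% of Tomato- cells. Progenitor-like cells, with Fgf15 and Sfrp2 among their markers, made up 31.8% (27 to 36.8) of Tomato- and 0.612% (0.0742 to 2.19) of Tomato+ cells. Neurogenic precursor-like cells, with Atoh7 and Neurog2 among their markers, made up 15.2% (11.7 to 19.3) of Tomato- cells. Of the kept Tomato+ cells, 0 were in that class, where 3 cells would make 0.917% (upper end of the exact interval 1.12%). An unnamed cluster, led by genes such as Tfap2b, Prdm13, Prox1 and Neurod1 that are known from amacrine, horizontal and photoreceptor precursors, held 20.7% (16.7 to 25.3) of Tomato- and 2.14% (0.865 to 4.36) of Tomato+ cells. By the naming rule it also had 7 of 12 RGC markers raised, more than of any other list, and its name was withdrawn for its leading genes. The rule on leading genes was set after the clusters had been seen. Had the cluster kept the RGC name, its 20.7% of Tomato- cells would have been added to the 32.3%.

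**Figure D1:**
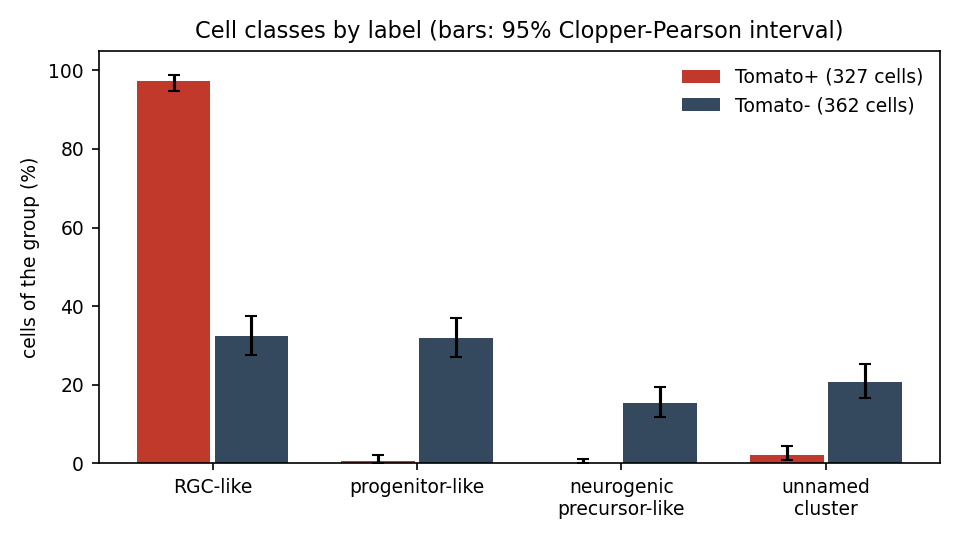
Share of cells in each class (percent, y axis starting at 0) in Tomato+ and Tomato- cells, with exact Clopper-Pearson 95% intervals as error bars. RGC-like cells made up 97.2% of Tomato+ and 32.3% of Tomato- cells, while progenitor-like cells made up 0.612% and 31.8%.

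Over single title numbers the RGC-like share ranged from 86.8 to 100% in Tomato+ and from 22.9 to 42.9% in Tomato- cells, without overlap. RGC-like cells had a median total of 272691 in Tomato+ and 332260 in Tomato- cells. The RGC-like clusters 0, 1, 2 and 6 held 29.7%, 9.17%, 42.2% and 16.2% of the kept Tomato+ cells, and 3.31%, 9.67%, 10.5% and 8.84% of the kept Tomato- cells. The difference in RGC-like share between the groups was 64.9 percentage points, and 41.4 points by marker counts.

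Across all retained cells, Tomato+ cells had higher levels of RGC-associated genes and lower levels of genes of dividing progenitors. Ephb1, the receptor that mediates repulsion of uncrossed RGC axons from the midline, had 147.9 CPM in Tomato+ and 18.4 CPM in Tomato- cells (log2 ratio 2.48, SD 0.82). Eomes, a T-box factor of RGC subtypes, had 213.8 against 28.5 CPM (2.54, SD 1.16). The retinoid-binding protein gene Crabp1 had 1269 against 242.3 CPM (2.34, SD 1.16). Ubash3b, with 350.9 against 62.8 CPM (2.31, SD 0.96), and Lgi2, with 55.7 against 4.00 CPM (2.23, SD 0.63), were also among the 10 highest by the rule used. Top2a, the topoisomerase of dividing cells, had 21.3 CPM in Tomato+ and 994 CPM in Tomato- cells (-5.01, SD 1.06). Ccnd1, which encodes cyclin D1, had 24.3 against 957 CPM (-4.82, SD 1.12). Fgf15, a growth factor gene of retinal progenitors, had 16.4 against 720 CPM (-4.79, SD 1.20), and the Notch effector Hes1 had 7.46 against 420 CPM (log2 ratio -4.62). The other 6 lowest genes were Cenpf (-4.92), Mki67 (-4.56), Cenpe (-4.34), Apoe (-3.99), Ube2c (-3.95) and Nusap1 (-3.92). Apoe was -2.43 without title number 12. All 20 ranked genes differed by more than their SD between title numbers.

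The highest log2 ratios among all retained cells belonged to globin genes. Hbb-y had 986 CPM in Tomato+ and 1.32 CPM in Tomato- cells (6.46, SD 3.66), followed by Hba-a1 (4.91, SD 3.05), Hba-x (4.67) and Hba-a2 (3.94). These values came from few cells: the 5 Tomato+ cells with the most counts held 96.99% of the Hbb-y and 94.9% of the Hba-a1 counts of the group. Without 7 Tomato+ cells that had at least 100 Hbb-y counts, the log2 ratio was 0.47 for Hbb-y, 0.26 for Hba-a1, 0.17 for Hba-x and 0.17 for Hba-a2. The erythroid marker list, whose median was 2.65, had a median of 0.09 without them. The pseudocount of 10 CPM holds ratios of such low values near 0. Over all kept cells, those 7 included, at least 1 Hbb-y count was found in 39.8% of Tomato+ and 17.96% of Tomato- cells. After thinning the shares were 25.5% and 8.59%, so low globin counts were also more widespread in Tomato+ cells.

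Of the genes tied to the uncrossed or the crossed RGC projection, some differed little over all cells, where the mix of cell types also enters. In the ipsilateral list, Igf1 was 2.21 (SD 1.44) with 293.4 CPM in Tomato+ and 55.6 CPM in Tomato- cells. Zic5 was 0.38 (SD 1.00), and -0.07 when each cell was weighted equally. Zic2 was -0.02 (SD 0.41), Zic1 -0.13 (SD 0.89) and Boc -0.39 (SD 0.56), the last being -0.20 without title number 18. In the contralateral list, Nrp1 was 1.20 (SD 0.60), Nrcam 0.72 (SD 0.39) and Plxna1 0.59 (SD 0.61). Pou4f1 was 0.08 (SD 0.76), Isl2 -0.08 (SD 1.28) and Igfbp5 -1.26 (SD 1.30). Zic2 and Isl2, both near 0, lay on the other side of 0 under TMM scaling, at 0.0016 and 0.015.

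Among the lists of genes compared over all cells, axon growth and cytoskeleton genes were higher in Tomato+ cells and cell cycle, Notch and signalling genes of progenitors were lower. Medians of log2 ratios are given with their percentile among 10000 random lists of matched expression, as a description of these libraries. The axon growth list had a median of 1.06 (percentile 100) with 15 of 15 genes above 0, among them Mapt with 1853 against 658 CPM and Nefm with 2730 against 1015 CPM. The cell cycle list had a median of -3.15 (percentile 0) with 17 of 17 genes below 0. The Notch list had a median of -1.42 (percentile 0) with 11 of 12 genes below 0, including Hes5 at -3.06 and Hes6 at -2.66. The Wnt and Sonic hedgehog list had -1.20 (percentile 0), with 10 of 14 genes below 0, among them Sfrp2 at -2.53 and Fzd5 at -2.13, and Shh at 0.42 above 0.

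The ipsilateral list, which includes Slc6a4 itself, had a median of 0.38 (percentile 98.5) over all cells. It was 0.18 (percentile 87.15) without Slc6a4 and 0.02 when cells were weighted equally. The contralateral list had 0.33 (percentile 93.5). The serotonin list, which also includes Slc6a4, had 0.20 (percentile 97.2), or 0.12 (percentile 90.5) without Slc6a4. In it, the vesicular monoamine transporter gene Slc18a2 had 314.6 against 131.5 CPM and the serotonin receptor gene Htr1b was 1.08. The axon guidance receptor list had 0.14 (percentile 95.6), with L1cam at 1.11 and Dcc at -1.23. Of the lists for retinal position, the ventral list had -0.20 (percentile 29.5), the dorsal list -0.04 (percentile 42.9), the temporal list -0.02 (percentile 58.7) and the nasal list -0.06 (percentile 55.7). Members of these lists went both ways, with Epha6 at 1.47 and Epha3 at -1.77 in the temporal list. The insulin-like growth factor (IGF) list had -0.17 (percentile 27.8).

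Several lists of cell type markers, and the lists of dissociation stress and of hypoxia and glycolysis genes, differed with the label as well. The mix of cell types differs between the groups and enters these values, so they do not show a difference in handling. The RGC marker list had a median of 1.06 (percentile 100), with Sncg at 6572 CPM in Tomato+ and 2491 CPM in Tomato- cells. The progenitor list had -3.06 (percentile 0), the neurogenic precursor list -1.99 (percentile 0), the photoreceptor list -0.96 (percentile 0.03) and the amacrine list -0.61 (percentile 0.08), which was -0.99 without title number 14. The microglia or macrophage list had -1.53 (percentile 0), or -0.70 without title number 12, and the endothelial list -0.58 (percentile 0.15). The ciliary margin list had -0.47 (percentile 2.13), or -0.28 without title number 11. The horizontal cell list had -0.25 (percentile 13.4), or -0.14 without title number 12. The optic stalk or astrocyte list had -0.12 (percentile 5.97), the mesenchyme list -0.09 (percentile 21.3), the pigment epithelium list -0.02 (percentile 47.4) and the lens list 0.04 (percentile 75.3). In these lists and the microglia or macrophage list, no gene had at least 5 counts in 10% of a group's cells. The endothelial and ciliary margin lists had 1 such gene each. Their medians and percentiles rest largely on low counts. Dissociation stress genes had -0.79 (percentile 0), with Fos at 20.7 against 168.6 CPM. Hypoxia and glycolysis genes had -1.07 (percentile 0) with 9 of 9 genes below 0, among them Ldha at 250 against 684 CPM.

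Within the RGC-like class, Tomato+ cells were compared with Tomato- cells to ask what separates RGCs that carry the label from those that do not. Slc6a4 was higher within this class too, at 105.8 CPM (103.6 to 108.02) in Tomato+ and 0.767 CPM (0.510 to 1.11) in Tomato- cells (log2 ratio 3.43, SD 0.45). At least 5 Slc6a4 counts were found in 37.4% (32.1 to 42.99) of Tomato+ and 0.855% (0.022 to 4.67) of Tomato- RGC-like cells. Ephb1 was higher in Tomato+ RGC-like cells, at 150.4 CPM (147.8 to 153.01) against 35.2 CPM (33.3 to 37.2), a 4.27-fold difference (log2 1.83, SD 1.26). Zic5, a zinc finger gene next to Zic2, was higher at 67.5 CPM (65.8 to 69.3) against 10.7 CPM (9.65 to 11.8), with a log2 ratio of 1.91 (SD 1.18). Pou4f1, which encodes the RGC transcription factor Brn3a, was lower at 127.9 CPM (125.5 to 130.3) against 264.2 CPM (258.95 to 269.5), with a log2 ratio of -0.99 (SD 0.73).

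These genes of the ipsilateral and contralateral lists were the ones whose difference in RGC-like cells exceeded the SD between title numbers. Unlike Slc6a4, the other genes overlapped between the groups over single title numbers. Ephb1 lay between 97.4 and 296.1 CPM in Tomato+ and between 0.244 and 124.7 CPM in Tomato- RGC-like cells. Zic5 lay between 17.4 and 144.6 against 0.323 and 45.4 CPM, and Pou4f1 between 74.4 and 194.8 against 131.1 and 471.3 CPM. At least 5 counts of Ephb1 were found in 55.3% (49.7 to 60.9) of Tomato+ and 17.9% (11.5 to 26.1) of Tomato- RGC-like cells, beside 7.83% of progenitor-like Tomato- cells. For Zic5 the shares were 28.6% (23.7 to 33.9) and 9.40% (4.79 to 16.2), beside 26.96% of progenitor-like Tomato- cells. For Pou4f1 they were 50% (44.4 to 55.6) and 75.2% (66.4 to 82.7), beside 10.4% in progenitor-like cells. The log2 ratio of Zic5 was 1.11 without title number 14, nearly as low without title number 2, and 0.80 with cells weighted equally. That of Pou4f1 was -0.58 without title number 2, and the share of RGC-like cells with at least 1 Pou4f1 count, 73.3% against 86.3%, was then 2.99 points higher in Tomato+ cells.

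**Figure D2:**
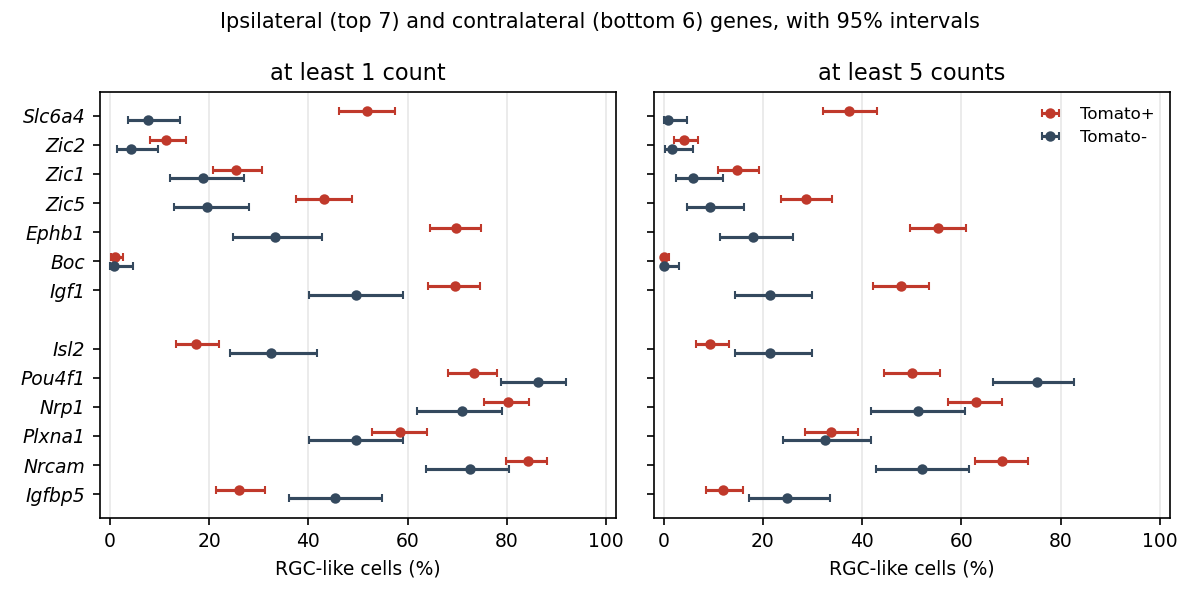
Share of RGC-like cells (percent) with at least 1 and at least 5 counts of 7 ipsilateral and 6 contralateral genes in Tomato+ and Tomato- cells, with exact Clopper-Pearson 95% intervals. At 5 or more counts, Ephb1 was found in 55.3% of Tomato+ and 17.9% of Tomato- cells, and Pou4f1 in 50% and 75.2%.

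The remaining genes of both lists differed by less than their SD between title numbers in RGC-like cells. Igf1, known from the ipsilateral programme, had 298.6 against 131.3 CPM (log2 ratio 1.13, SD 1.75), with at least 5 counts in 47.8% (42.2 to 53.4) and 21.4% (14.3 to 29.9) of cells. Zic2, which directs the uncrossed projection, was low in both groups at 2.26 and 0.713 CPM (0.19, SD 0.35), with at least 5 counts in 4.09% and 1.71% of cells. Zic1 was 0.45 (SD 1.05), or -0.26 without title number 7. Boc had 5 counts in Tomato+ and 3 in Tomato- cells, too few for a ratio. Isl2, a factor of crossed RGCs, was -0.78 (SD 1.67) with at least 5 counts in 9.43% and 21.4% of cells. Nrcam was 0.43 (SD 0.56), Plxna1 0.35 (SD 0.58) and Nrp1 0.25 (SD 0.58). Igfbp5 was -1.46 (SD 2.00), and 0.34 without the mitochondrial filter.

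On GRCm38, Zic5 lies on chromosome 14 from 122456795 to 122465677 (minus strand) and Zic2 on the same chromosome from 122475435 to 122479852 (plus strand), with 9757 bases between them. Pou4f1 lies on chromosome 14 from 104461676 to 104467999 (minus strand). Ephb1 lies on chromosome 9 from 101922128 to 102354693 (minus strand), Igf1 on chromosome 10 from 87858265 to 87937042 (plus strand) and Isl2 on chromosome 9 from 55538672 to 55546180 (plus strand). Counts are per protein-coding gene, without exon or isoform.

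Of the other genes among the 10 highest in RGC-like cells, Lgi2 had 56.8 CPM (55.2 to 58.4) in Tomato+ and 5.92 CPM (5.16 to 6.76) in Tomato- RGC-like cells (2.07, SD 0.73). The neuropeptide precursor gene Tac1 had 65.5 against 14.2 CPM (1.64, SD 1.31), and the GABA receptor subunit gene Gabra3 32.98 against 3.84 CPM (1.64, SD 1.03). Sv2b, a synaptic vesicle gene, was 1.59 (SD 1.14), and Eomes was 1.54, less than its SD of 1.66. The globins Hbb-y (5.93) and Hba-a1 (4.12) also ranked among the highest, and were 0.36 and 0.24 without the cells that held at least 100 Hbb-y counts.

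Of the 10 lowest genes in RGC-like cells, the cyclin gene Ccnd1 had 7.20 against 78.9 CPM (-2.37, SD 0.72), with at least 5 counts in 5.03% of Tomato+ and 33.3% of Tomato- cells. Fgf15 was -1.92 (SD 1.11), or -3.12 without title number 10, and Top2a was -1.86 (SD 1.19). Otx2, a factor of photoreceptor precursors and progenitors, was -1.63 (SD 1.14), and -0.92 without title number 5. Mki67 was also -1.63, less than its SD of 1.64, and -0.86 when averaged over shared title rows. The axonal adhesion gene Cntn2 had 67.05 against 292.3 CPM (-1.97, SD 1.47), and was -0.85 without the mitochondrial filter. Ppp1r17 was -2.05 (SD 1.16), and Pou3f1 was -1.74 (SD 1.07) or -0.40 without that filter. Cntn2 and Ppp1r17 lead cluster 1, which held 30 Tomato+ and 35 Tomato- cells. Kdr was -1.57 (SD 1.27) and Casz1 -1.56 (SD 1.19).

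Among the gene lists in RGC-like cells, the ipsilateral list was higher in Tomato+ cells, with a median of 1.13 (percentile 100) and 6 of 7 genes above 0, of which Slc6a4, Ephb1 and Zic5 exceeded their SD between title numbers. Without Slc6a4, whose driver gives the label, the median was 0.79 (percentile 100). With it, the median stayed between 0.89 and 1.62 when any 1 title number was left out, and was 0.75 when both groups were averaged over the same rows of the titles. The contralateral list had a median of -0.26 (percentile 4.20), with 3 genes above and 3 below 0, and it was 0.20 when RGC-like cells were taken by marker counts. The serotonin list had 0.24 (percentile 99.5) with 8 of 8 genes above 0, of which Slc6a4 alone exceeded its SD between title numbers. Htr1b had 28.6 against 14.5 CPM (0.65, SD 1.08), Slc18a2 was 0.30 (SD 0.51), and the Tph1 counts came from 1 cell. Genes known from the temporal retina had 0.29 (percentile 97.3) with 4 of 4 above 0, each by less than its SD, including Epha6 at 0.79 (SD 1.17) and Foxd1 at 0.39 (SD 0.72). The median was 0.10 without title number 2, and Epha3 was found in 3.46% of Tomato+ and 7.69% of Tomato- cells. Genes known from the nasal retina had -0.44 (percentile 2.37) with 3 of 4 below 0, including Efna5 at 58.4 against 119.4 CPM (-0.92, SD 0.91) and Hmx1 at -0.41 (SD 0.74), and the median was -0.24 without title number 14. The ventral list had -0.13 (percentile 11.1) and the dorsal list -0.03 (percentile 53.9).

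**Figure D3:**
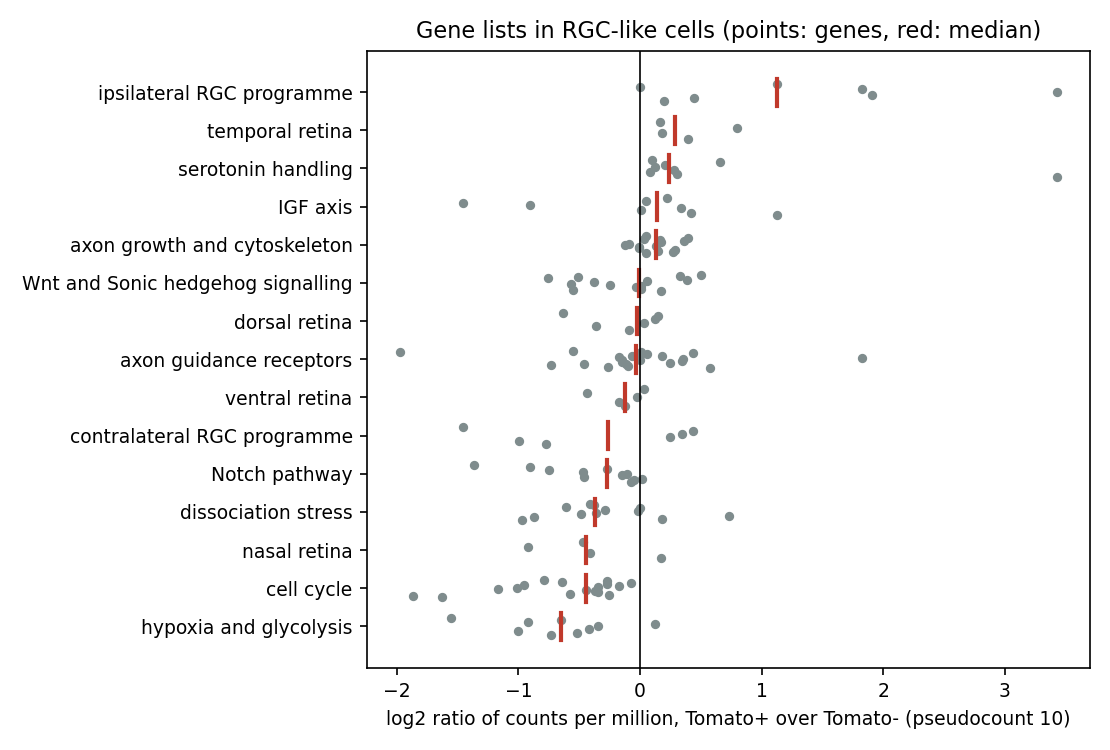
Log2 ratio of CPM (Tomato+ over Tomato-, pseudocount 10 CPM) in RGC-like cells for the genes of 15 lists, with points for genes and red marks for medians. The median was 1.13 for the ipsilateral list, -0.26 for the contralateral list and -0.65 for the hypoxia and glycolysis list.

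Growth and signalling lists differed less between the RGC-like groups than between all cells. Axon growth genes had a median of 0.13 (percentile 96.9), with Nefm at 0.39 and Mapt at 0.36. Axon guidance receptors had -0.03 (percentile 32.7), with Ephb1 at 1.83 and Cntn2 at -1.97 farthest from 0, followed by Dcc at -0.73 and Robo1 at 0.58. The Notch list had -0.27 (percentile 0.24) with 10 of 11 genes below 0, including Mfng at -1.36. The Wnt and Sonic hedgehog list had -0.01 (percentile 37.6), and the IGF list had 0.14 (percentile 91.1) with a mean of -0.02. The cell cycle list had -0.44 (percentile 0.01) with 17 of 17 genes below 0, and it lay between -1.28 (without title number 10) and -0.34 over the leave-one-out runs.

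Some lists of markers of other cells and of handling differed within the RGC-like class too. The progenitor list had -0.74 (percentile 0), which was -1.51 without title number 2 and -0.42 without title number 13. The neurogenic precursor list had -0.67 (percentile 0), which was -1.40 without title number 2 and -0.22 without title number 20. The amacrine list had -0.50 (percentile 0.12), with Tfap2b at -1.15, and the horizontal list -0.33 (percentile 1.18), or -0.16 over shared title rows, with Prox1 at -1.20. The endothelial list had -0.42 (percentile 0.27), the photoreceptor list -0.21 (percentile 5.50), the optic stalk or astrocyte list -0.07 (percentile 13.7) and the ciliary margin list 0.19 (percentile 97.54). The optic stalk or astrocyte list rests on 1 gene with counts. In the amacrine, endothelial and ciliary margin lists, 1 gene each had at least 5 counts in 10% of a group's cells. The RGC marker list itself had 0.09 (percentile 86.3). The erythroid list, which holds the globin genes described above, had 2.19 (percentile 100). Near 0 were the microglia or macrophage list at 0.002, the mesenchyme list at 0.005, the pigment epithelium list at 0.03 and the lens list at 0.08. In the erythroid list and these lists near 0, no gene had at least 5 counts in 10% of a group's cells. Dissociation stress genes had -0.37 (percentile 0.09), with Fos at 13.2 against 35.4 CPM, and the median was -0.19 without title number 13 and -0.16 over shared title rows. Hypoxia and glycolysis genes had -0.65 (percentile 0) with 8 of 9 below 0, including Ldha at 244.97 against 502.4 CPM, Pdk1 at 8.80 against 45.2 CPM and Vegfa at 16.6 against 40.3 CPM. That median was -0.40 without title number 20. The number of Tomato- RGC-like cells depended on how the class was defined, with 85 cells by marker counts and the largest number without title numbers 8 and 10. Values given without a title number come from classes drawn again, so they also reflect such changes in the class.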

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

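Slc6a4 was also present in cells outside the comparisons. Among the 73 Tomato+ cells left out for their mitochondrial share, 12 cells, or 16.4% (exact 95% interval 8.79 to 26.95), had at least 5 Slc6a4 counts at a median total of 94705. Of the 38 Tomato- cells left out in the same way, 0 had at least 5, at a median total of 88370, where 3 cells would make 7.89%. The exact interval for these reaches 9.25%, so the intervals of the groups overlap. This result is listed because the signal lies in cells that the comparisons do not use and its share is above that of the matching Tomato- cells, by intervals that overlap. At least 1 count was found in 26.03% and 13.2% of these cells. No explanation was tested.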

How the results depend on the processing

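Alternatives chosen after the data were seen were leaving out title numbers 8 and 10, the cells with at least 100 Hbb-y counts or the RGC-like cluster with the lowest 18S share, a stricter marker-count class, averages over the title rows that hold cells of both groups, and lists without Slc6a4. The main results are the share difference and log2 ratio of Slc6a4 over all and RGC-like cells, the RGC-like share difference, the cell cycle median over all cells and the ipsilateral median in RGC-like cells. Most of them thus concern Slc6a4, whose driver gives the label. Of their values under settings other than leave-one-out, 84 stayed within their spread or interval and 10 moved, and over the leave-one-out runs 7 moved. The RGC-like share difference, 64.9 points, was 71 without the mitochondrial filter, 70.6 at Leiden resolution 0.5, 47.4 with 10 principal components, 58.6 with the compared lists among the variable genes, 41.4 with the marker-count class and 46.2 without title numbers 8 and 10. It ran from 46.2 (without title number 2) to 70.8 (without title number 5) over the leave-one-out runs, and was 46.3 without title number 14. The share difference of Slc6a4, 44.96 points, was 36.4 at 5 or more counts. With a pseudocount of 1, the log2 ratio of Slc6a4 was 6.08 over all cells and 5.92 in RGC-like cells, and the cell cycle median was -4.51, since a smaller pseudocount stretches low values. The share difference of Pou4f1 in RGC-like cells, -13.1 points, reversed to 3.67 without title numbers 8 and 10 and ran from -18.6 to 2.99 over the leave-one-out runs, the highest without title number 2. Apart from the pseudocount, the cause was not tested. For the genes and lists named, 2234 values under other settings stayed within their spread or interval and 5.82% moved, and over the leave-one-out runs 3457 stayed and 62 moved. A log2 ratio counted as staying if it moved by less than its SD between single title numbers. Pooled values seldom move that far, so these counts say little about stability. Igfbp5 in RGC-like cells, at -1.46 with an SD of 2.00, counted as staying though it lay above 0 without the mitochondrial filter. The Pou4f1 share difference was the 1 value in each set that turned from a difference beyond its interval to the other side of 0. Counting also differences that lay within their spread, 3.07% of the values under other settings and 3.25% over the leave-one-out runs lay on the other side of 0, none of them a main result. Between 9 and 20 of the 20 ranked genes over all cells, and between 10 and 20 in RGC-like cells, were shared with the main ranking.

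Depth and class size limit the RGC-like comparison, where the number of Tomato- cells was lowest, at 85, in the marker-count class and highest without title numbers 8 and 10. Requiring at least 500 genes kept the same 689 cells, the limit on very many genes called 0 cells, and the first marker rule took in all 689 cells, so these settings say nothing about stability. No paired analysis was possible by animal or litter, because none is named for any cell. Cells could be matched only by the row numbers in the titles, which occur in both groups and whose meaning is not given. Averaged over shared rows, the RGC-like share difference was 65.6 points, in the same direction in 40 of 40 rows, and the median of the ipsilateral list in RGC-like cells was 0.75.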

Other observations

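The genes in this paragraph and the next, broken down by cluster, were chosen after their values were seen. Slc6a4 was spread over the RGC-like clusters of Tomato+ cells rather than held by 1 of them, with at least 5 counts in 40.2% of cells in cluster 0, 46.7% in cluster 1, 38.4% in cluster 2 and 24.5% in cluster 6. Depth differed between these clusters, with median totals over both groups of 264374, 317161, 326260 and 151648 in the same order. Pou4f1 was found at that level in 59.8%, 63.3%, 44.9% and 37.7% of the Tomato+ cells of these clusters, and in 75%, 71.4%, 81.6% and 71.9% of the Tomato- cells. Isl2 was found in 9.28%, 10%, 12.3% and 1.89% of the Tomato+ cells and in 0%, 22.9%, 31.6% and 15.6% of the Tomato- cells, where cluster 0 holds 12 cells. Tomato+ RGC-like cells thus carried Pou4f1 in a large share of each of these clusters.

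Zic5 was not restricted to RGC-like cells. In Tomato- cells it had at least 5 counts in 41.8% of neurogenic precursor-like cells (108.8 CPM) and 26.96% of progenitor-like cells (64.4 CPM), above the 9.40% of Tomato- RGC-like cells. Opn4, the melanopsin gene of intrinsically photosensitive RGCs, had at least 5 counts in 5.66% (3.39 to 8.80) of Tomato+ and 1.71% (0.208 to 6.04) of Tomato- RGC-like cells, so the intervals overlap. Pou4f2 had at least 5 counts in 66.4% and 51.3% of RGC-like cells.

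Of the tests that follow, the one on low-level transfer was chosen after its result was seen, and so was the breakdown of low counts by title number and row number. Progenitor and cell cycle genes were lower in Tomato+ than in Tomato- RGC-like cells. For counts passed between cells, the median difference over 28 genes in the share of cells with at least 5 counts was -5.81 points (-7.37 to -4.23). This cause required a value above -1 only if passed counts stay below 5 in a cell, which was not shown. The range also covers genes and not cells, so the test does not decide and this cause stays open. Doublets of an RGC and a progenitor may contribute, since 12 Tomato- cells held 60.4% of the CPM of these genes, between the 40% and the 70% set in advance as marks against and for doublets. Free progenitor RNA at 1 level in every cell stays open as well, with an upper over lower quartile of the excess of 1.91 (1.47 to 3.56). Counts passed between cells, doublets, free RNA and a difference in maturity between labelled and unlabelled RGCs, which was not tested, cannot be told apart here.

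Most globin counts of Tomato+ cells came from few cells, but low counts were also found in more Tomato+ than Tomato- cells. At least 5 Hbb-y counts were found in 10.1% of Tomato+ and 1.10% of Tomato- cells. RNA of red blood cells is a candidate source: 100% of the 7 Tomato+ cells with at least 100 Hbb-y counts also had at least 5 counts of Hba-a1 or Hba-x. These cells lay in 3 of the 10 Tomato+ title numbers, the most that a source tied to a few title numbers allowed. The data hold no mark that would separate free red cell RNA from red cells sorted with the neuron, and a biological difference in the label was not tested.

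Hypoxia and glycolysis genes were lower in Tomato+ than in Tomato- RGC-like cells, with a median of -0.65. Poor libraries among the Tomato+ cells, taken as title numbers 8 and 10 and cluster 6, were unlikely to be the whole cause. Without them the median was -0.58 (-1.18 to -0.41), by a range over genes and not cells, in 230 Tomato+ and 85 Tomato- cells. Cluster 6 held cells of both groups, 53 Tomato+ and 32 Tomato-. Its median total was 151648, with a mitochondrial share of 11.5% and an 18S share of 0.918%. For progenitor RNA in Tomato- RGC-like cells, taking out a share of 2.11% of the progenitor-like profile left -0.51 (-0.98 to -0.32). This cause required a median above -0.2, but the range crossed the mark of -0.4 set in advance against it. The correction also assumed 1 share for every gene, while the quartiles over the 28 progenitor and cell cycle genes were 1.81% and 3.44%. The test therefore does not decide. The correction took the median of the progenitor and cell cycle genes from -0.56 to -0.01. That follows from its construction, since the share taken out was set from these same genes. A contribution of progenitor RNA to part or all of the difference in the hypoxia list stays open. A difference in metabolism between labelled and unlabelled RGCs stays open, as untested.

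Low counts were also compared by the position given in the title. For genes with at least 1000 counts in 1 to 5 cells of 1 group, 1 to 4 counts were found in 15.49% (14.6 to 16.4) of gene and cell pairs that shared a title number with such a cell and in 16.3% (14.5 to 18.2) of those that shared a row number. Of pairs that shared neither, 12.6% (12.3 to 12.96) had them.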
